A study of Mus musculus with 9 samples.

How the data were processed

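The starting point was the deposited count matrices of the 7 RNA libraries, as UMI counts per barcode and feature, together with the authors' deposited tables that assign barcodes to clusters. Per the submitters' processing notes the counts were made with Cell Ranger on the mm10 mouse genome, and versions were not given in the sources used here. Each matrix held 28000 RNA features, of which 2 were reporters without a UMI, so 27998 genes were used. The Epo and saline matrices also held the counts of 26 antibody tags, which is where the 2 antibody samples were read from. Raw reads were not used here.

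Cells were grouped by the authors' cluster names, and by their names the clusters were gathered into an erythroid, a granulocytic, a monocytic, a macrophage-named and an other class, as laid down before the data were examined. The cluster table of the sorted and unsorted experiment listed some barcodes again under a second library, and those 6750 second listings were not used. Barcodes without a cluster were left out of the comparisons. No further filter on UMIs, genes or mitochondrial share was applied in the main analysis, because the authors had already chosen cells and no barcode held fewer than 500 UMIs. For the 56 symbols listed under more than 1 gene identifier, the identifier of the reference gene table carried the plain symbol.

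UMIs were summed over the annotated cells of a class, or over all annotated cells of a library for the sorts, and scaled to CPM, the UMIs of a gene per 1e6 gene UMIs. A log2 ratio was taken with 0.5 UMI, scaled to the depth of each group relative to the mean depth, added to each sum. Intervals on ratios are exact conditional binomial 95.0% intervals, and intervals on shares are exact binomial. These intervals hold counting error only. With 1 library per group there is no replicate check in this series apart from the 2 unsorted libraries, so no test between groups was made. A gene entered a comparison with at least 10 UMIs over the groups compared. Groups of fewer than 20 cells were not compared. A gene without a UMI in a sort is given as a bound, the fold by which it was at least lower, taken against a floor of 3 UMIs.

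The genes named below were chosen by a rule fixed before the data were examined. In each comparison the 8 highest and 8 lowest log2 ratios were taken among genes with at least 200 UMIs whose interval left out a ratio of 1. Haemoglobin, ribosomal, mitochondrial, immunoglobulin and T-cell receptor segment, sex-linked and unnamed-model genes were kept out of this choice. For a sort the value also had to lie outside the range of the unsorted libraries. From each of 28 gene lists, fixed at the same time from general knowledge, the members with most UMIs and with the largest ratios were added, provided they had 100 UMIs. For each list the median log2 ratio of its measured members was placed among the medians of 10000 random lists matched for expression in 20 bins, and the percentile is given. Fixed list members that found no matching symbol were not analysed here. Values of some single genes chosen by the rule are not reported here.

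A named class was compared between groups only when none of its clusters had more markers of a different class than of its own. Markers were counted among the 10 genes of highest fold of each cluster, with 16 marker lists, so the rule does not weigh amounts of RNA. Erythroid clusters passed in both experiments. The erythroid cluster ERP2, and every erythroid cluster of the sorted experiment except ERP_c17, passed with no marker of any class among those 10 genes. In the Epo experiment the granulocytic cluster proNeu-1 had the eosinophil genes Epx and Prg2 among those 10 genes, against 1 marker of its own class. By amount its primary granule RNA was far higher, with Elane at 19219 CPM and Prg2 at 766 CPM with Epo. By the rule granulocytic genes are reported without it, and the macrophage-named and monocytic cells are reported by cluster. Among sorted cells the clusters Mac_c12 and Mac_c30 were led by plasmacytoid dendritic and stromal genes and are also reported by cluster.

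Antibody tags were compared within a library as the mean tag UMIs per cell of a cluster divided by the mean of all annotated cells of that library. 1 saline barcode with 103786 tag UMIs was left out of the tag means, a choice made after the data had been seen.

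The calculation was tested on known changes. Poisson UMI sums were simulated at the pooled expression and the depths of the erythroid and of the granulocytic class, with 100 genes raised 2-fold and 100 set to 0.5-fold. The medians found were 0.99 and -0.99 log2 in erythroid cells, with 94.0% and 96.0% of intervals holding the true value, and 1.011 and -1.00 log2 in granulocytic cells, with 93.0% and 90.0%. Among the genes left unchanged, 95.4% and 95.5% of intervals held a ratio of 1. Poisson sums meet the assumption of these intervals, so the simulation checks the calculation only. UMIs gathered in few cells, as for S100a8 in erythroid cells below, were not simulated, and the intervals do not hold the spread they add.

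Alternatives were run with a cell filter (1000 UMIs, 500 genes, 10% mitochondrial), with classes assigned by marker genes in place of the authors' clusters, with TMM scaling from edgeR, with haemoglobin left out of the totals, with each cell given equal weight, with 5 UMIs added, with 100 UMIs asked of list members, with genes at 0 set to their bound, with each unsorted library left out, and with doublets removed. Doublets were scored with Scrublet as run by scanpy, at an expected rate of 0.06 and a fixed seed. Its own threshold marked 1 Epo barcode and 248 saline barcodes, so it did not work evenly, and removing the highest scores (535 and 637 barcodes, at 0.8% per 1000 barcodes) was added.

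Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 and matplotlib 3.10.9, and edgeR 4.0.16. Gene positions are those of mm10.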

Results

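An erythroblastic island is a central macrophage with developing red cells attached to it, and the series asks which cells sit in such islands of mouse bone marrow. Marrow of C57BL/6J mice of either sex, 3 to 6 months old, was flushed from tibiae, femurs and pelvic bones. Cell clusters were collected from the 3% layer of a bovine serum albumin gradient and taken apart with 10 mM EDTA for 15 minutes. Of 9 samples, 7 are RNA libraries and 2 are antibody samples read in the same cells. In 1 experiment mice received erythropoietin (Epo), the hormone that drives red cell production, at 1200 U/kg once daily for 10 days, or saline. These 2 groups, with 1 library each, were read by CITE-Seq, which counts RNA and antibody tags bound to surface proteins in the same cell. The other experiment used single-cell RNA-Seq on unsorted islands (2 libraries) and on cells sorted for CD11b, an integrin of myeloid cells, for CD71, the transferrin receptor, or for F4/80, a macrophage surface protein (1 library each).

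The Epo library held 8176 barcodes, 6889 of them with a cluster from the authors, and the saline library 8922 and 7515, at a median of 9327 and 9719 UMIs per barcode. The unsorted libraries held 5485 and 7715 barcodes at medians of 5994 and 6192 UMIs. The CD11b+, CD71+ and F4/80+ libraries were smaller, with 2789, 1498 and 1350 barcodes and medians of 4607, 6475.5 and 6152 UMIs. Haemoglobin genes made up 22.01% and 21.4% of UMIs in the unsorted libraries, 59.8% in the CD71+ library, and 0.263% and 0.103% in the Epo and saline libraries, so red cells rich in haemoglobin RNA are few in the CITE-Seq data. Xist, transcribed from the inactive X chromosome, stood at 476, 475 and 1411 CPM in the CD11b+, CD71+ and F4/80+ libraries and at 636 CPM in unsorted library 1, against 0.234 CPM in unsorted library 2. Genes of the Y chromosome showed the reverse, with 141 CPM in unsorted library 2 and 0.0241 CPM in unsorted library 1. The sorts and unsorted library 1 thus share sex RNA, so sorted log2 values below are given against the mean of the unsorted libraries and, after it, against unsorted library 1. The Epo and saline libraries both held Y-linked RNA (119 and 95.1 CPM).

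The first question is which cells filled the islands of Epo-treated and saline-treated mice. Erythroid cells made up a larger share of the Epo library and granulocytic cells a smaller share. The erythroid share was 7.35% of annotated cells (95% interval 6.74 to 7.99, 506 cells) with Epo and 2.66% (2.31 to 3.05, 200 cells) with saline, a 2.76-fold difference. The granulocytic share was 30.3% (29.2 to 31.4) against 45.7% (44.6 to 46.9), and the difference of -15.5 points was the same without the cluster proNeu-1. For each cell of the granulocytic clusters, proNeu-1 included, there were 0.243 erythroid cells with Epo and 0.0582 with saline. All intervals in this report hold counting error only.

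Both erythroid clusters were larger in the Epo library, ERP1 with 4.30% against 1.57% and ERP2 with 3.05% against 1.09% of annotated cells. Their balance was alike, since ERP1 held 58.5% of erythroid cells with Epo and 59.0% with saline. In the granulocytic cells the share with Epo over that with saline was smaller in more mature clusters (0.727 in preNeu-2, 0.523 in preNeu-3, 0.361 in immNeu), though the difference in points was largest in preNeu-3. The immature neutrophils (immNeu) were 1.84% (1.54 to 2.19) against 5.11% (4.62 to 5.63), preNeu-3 8.36% against 16.0% and preNeu-2 11.7% against 16.1%. The earlier proNeu-2 (4.83% and 5.07%) was nearly equal, as was proNeu-1 (3.53% and 3.49%). Among B cells, precursors named Pre-B were 5.88% against 12.0%, whereas Pro-B cells were 2.64% against 1.66%. B cell_c21 had the smallest share with Epo relative to saline of all clusters (0.232% against 1.40%). B cell_c16, whose leading genes include Jchain of plasma cells, was 0.755% against 0.479%. Natural killer cells were 1.61% and 0.798%, dendritic cells 2.64% and 1.48%, and multipotent progenitors (HSCP-MPP) 1.45% and 0.998%. All 4 clusters named for monocytes were larger with Epo, the largest being Mono_c15 at 14.6% against 11.0%. Of these, Mono_c13 and Mono_c19 each had 1 marker of a different class and 0 of their own among their 10 genes of highest fold. Shares of a library sum to a fixed total, so the smaller granulocytic share by itself makes every other share larger. How far the larger shares of monocyte, dendritic, natural killer and progenitor clusters go beyond that was not tested. The macrophage cluster Mac_c9 held 83 cells, or 1.20% (0.961 to 1.49), with Epo and 18 cells, or 0.240% (0.142 to 0.378), with saline.

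**Figure D1:**
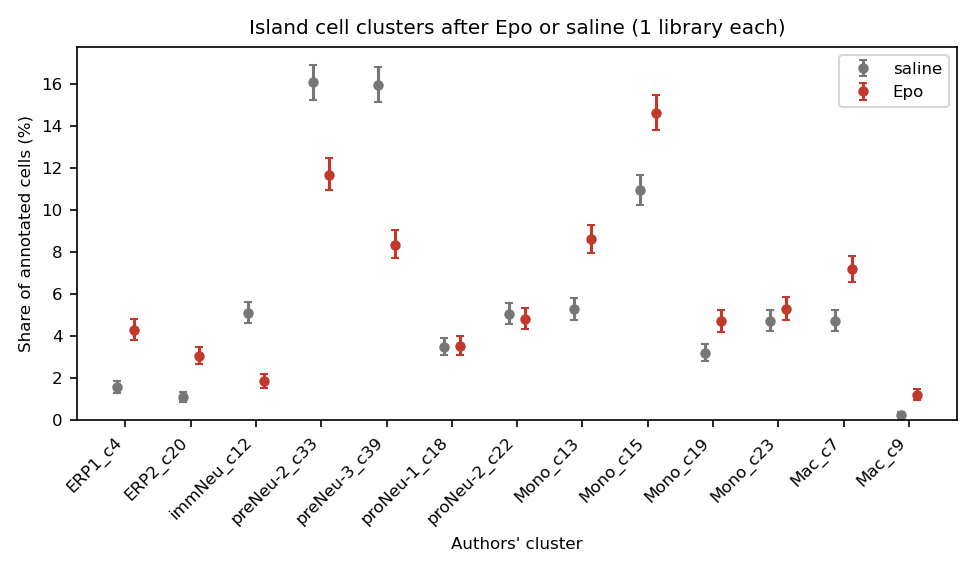
Share of annotated cells (%) in the authors' erythroid, granulocytic, monocytic and macrophage-named clusters, saline in grey and Epo in red. Bars are exact 95% intervals, with 1 library each. Erythroid clusters and Mac_c9 stand higher with Epo, late neutrophil clusters lower.

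The second question is which genes differed within the erythroid cells. Over both erythroid clusters together, iron import genes stood somewhat higher with Epo. So did the fixed list of dissociation and immediate early genes, called immediate early genes below. Haem synthesis genes were divided, and RNA typical of neutrophils, monocytes and B cells stood far lower. The clusters differed in direction for several red cell genes, so their separate values follow the pooled ones. Log2 ratios are Epo over saline, and the median over all genes was -0.07. The percentile places a list median among random lists of matched expression.

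Among single genes, the clearest higher values with Epo were for Cda, which deaminates cytidine (2.93, interval 2.21 to 3.81, 290 against 15 UMIs), Plek2, an actin-organising protein of late erythroblasts (2.65, 1.996 to 3.42), and Fabp5, a fatty acid carrier (2.40, 2.27 to 2.54, 341 against 64.4 CPM). Podxl, a sialomucin of early and stressed erythroid cells, reached 4.67 (2.97 to 7.91) with 144 UMIs against 2. Ptger3, a prostaglandin E receptor, was 1.60, and the linker histone gene H1f0 was 1.00. Cpd, a carboxypeptidase, was 0.99. The lowest named genes included Erdr1 (-2.53), Ifitm6 (-2.14), the granule-related Wfdc21 (-2.07), the lymphoid factor Ets1 (-2.03) and Mzb1 of B lineage cells (-1.87).

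Of the erythroid lists, iron import and handling had 7 of 12 members higher (median 0.18, percentile 99.5). Its leading member Tfrc, the transferrin receptor, was at 0.55 (0.49 to 0.61), the ferrireductase gene Steap3 was higher too, and the ferritin gene Fth1 was at 0.25. Haem synthesis had 6 of 8 members higher (0.11, percentile 85.4), with Uros at 0.34, but Alas2, which makes the first intermediate of haem in red cells, was lower (-0.37, -0.55 to -0.18). Haemoglobin itself had 1 of 4 genes higher (-0.19, percentile 0.45), with Hbb-bs at 0.02 and Hba-a1 at -0.26. Red cell membrane genes had 10 of 16 lower (-0.11, percentile 0.49), although Tmod1, which caps actin, was at 0.28. Ank1, which anchors the membrane skeleton, was at -0.26. Erythroid transcription factors and receptors were evenly split (6 of 12 higher, -0.02, percentile 33.6), with Lmo2 at 0.18, Zfpm1 at 0.06, Stat5b at -0.46 and Kit, the stem cell factor receptor, at -0.64. Autophagy and enucleation genes had 6 of 11 higher (0.10, percentile 90.3), Map1lc3b at 0.17 and the nuclear exporter Xpo7 lower.

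By cluster, ERP2 had more red cell RNA with Epo and ERP1 less. All 4 haemoglobin genes were higher in ERP2 (median 0.90, percentile 100) and lower in ERP1 (-0.40, percentile 0.015), with Hbb-bs at 1.38 (1.32 to 1.44) and -0.17 (-0.18 to -0.15). Haem synthesis had all 8 genes higher in ERP2 (0.40, percentile 100) and 5 of 8 lower in ERP1 (-0.07, percentile 4.98), where Alas2 was at -0.48. Membrane genes had all 16 higher in ERP2 (0.37, percentile 100) and 14 of 16 lower in ERP1 (-0.30, percentile 0), with Slc4a1 at 1.51 and -0.32. Erythroid factors followed the same split (0.21, percentile 98.0, and -0.27, percentile 0.02). The higher iron handling value came from ERP2 (0.49, percentile 100), not ERP1 (0.04, percentile 58.9), with Tfrc at 1.11 and 0.14. The cell cycle list was at 0.22 in ERP2 (percentile 99.6) and 0.05 in ERP1 (percentile 57.2), where Mki67 was at -0.24. RNA of other cell types moved along in ERP2, with Vpreb3 at -1.62, Cd79a at -1.49, Irf8 at -1.83 and Myb at -0.89, while in ERP1 Vpreb3 (-0.66, -1.55 to 0.23) and Cd79a (-0.37, -1.36 to 0.66) had intervals that held 0. These cluster comparisons rest on 210 and 82 cells of ERP2 and 296 and 118 cells of ERP1. In ERP2 the top 5% of cells held 74.1% of S100a8 UMIs with saline and 10.6% with Epo. The red cell values of ERP2 were therefore not told apart from a different cell make-up of that cluster in the saline library. Removal of doublets and equal weight per cell were not run by cluster for these lists.

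Targets of the Epo receptor and STAT5 stood near zero after 10 days of treatment, with 6 of 11 higher and a median of 0.01 (percentile 86.3), although Podxl, the gene with the largest ratio above, is a member. Epor, the receptor, was at 0.03 (-0.11 to 0.18), with 76.8 CPM against 75.1 CPM, which joins -0.32 (-0.51 to -0.12) in ERP1 and 0.42 (0.20 to 0.65) in ERP2. Pim1, a survival kinase induced by STAT5, was at -0.12, and Egr1 at -1.31. Cell cycle genes had 12 of 16 higher, within the range of random lists (0.10, percentile 87.7), with the spindle kinase Aurka at 0.49 (0.34 to 0.64), the nucleotide-making Rrm2 at 0.34 and Mki67 at -0.11. Immediate early genes had 9 of 12 higher (0.17, percentile 99.5), Fos at 0.24 and Zfp36 at -1.03. Hypoxia and glycolysis genes were evenly split (-0.02, percentile 46.6), with Gapdh at 0.17 and Pkm at -1.24.

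All 15 secondary and tertiary granule genes were lower in the Epo erythroid cells (median -1.43, percentile 0), led by Camp (-2.16) and Ltf (-1.79), which encode antimicrobial proteins of neutrophils. Primary granule genes had 8 of 9 lower (-0.72, percentile 0.01), with Ctsg, a granule protease, at -1.42. Mature neutrophil genes had 13 of 14 lower (-0.81, percentile 0.09), and S100a8, a calcium-binding protein abundant in neutrophils, was at -2.07 (-2.11 to -2.03), 460 against 1938 CPM. A few cells carried most of this S100a8 difference, since the top 5% of saline erythroid cells held 81.8% of the UMIs (45.4% with Epo) and the medians per cell were 9 with Epo and 13 with saline. S100a8 was at -0.95 in ERP1 and -3.20 in ERP2, and at -1.03 over both without the highest Scrublet scores. The granule lists were likewise lower mainly in ERP2, secondary and tertiary at -2.24 against -0.47 in ERP1, primary at -1.32 against 0.13, and mature neutrophil genes at -1.80 against -0.02. Granulocyte and monocyte transcription factors had 8 of 9 lower (-0.90, percentile 0), Spi1 at -1.05 and Irf8 at -1.43. B lineage markers had all 8 lower (-1.60, percentile 0), Vpreb3 at -1.65, so RNA of more than 1 foreign cell type moved together. The 3 measured megakaryocyte markers were lower (-1.24), as were both T and NK markers (-0.46), and 3 of 5 basophil and eosinophil markers were higher (0.20).

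The remaining lists in erythroid cells concern contact and signalling. Growth factor receptors had 14 of 16 lower (-0.68, percentile 0.46), Cxcr4, which answers the chemokine Cxcl12, at -0.72 and Igf1r at -0.60. Adhesion genes had 9 of 13 lower (-0.31), with the myeloid Itgam at -1.22 and the integrin Itgb1 at 0.22. Island macrophage genes (0.03, percentile 84.8), macrophage iron and haem recycling (-0.05, percentile 45.3), efferocytosis, which is the uptake of dying cells (-0.55, percentile 10.1), and growth factors and cytokines (0.11, percentile 93.1) lay within the range of random lists. Interferon response (-0.25, percentile 10.6) and MHC class II (-0.29, percentile 25.4) did too, though Cd74 was at -0.66 and Isg15 at -1.23, from -1.76 in ERP1 and 0.54 (-0.14 to 1.28) in ERP2. Sex-linked genes stood at 0.02, and no endothelial or stromal marker had enough UMIs.

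The third question is which genes differed within the granulocytic cells, taken without the cluster proNeu-1. Genes of early granules stood higher with Epo and genes of late neutrophils lower. Genes of macrophages and of red cell membranes also stood higher in these cells. In the Epo library the share of Mac_c9 was 5.03 times and that of erythroid cells 2.76 times the saline share. B lineage cells, B cell_c16 not counted, were 9.22% with Epo and 15.5% with saline. Whether RNA of other cell types came from the granulocytic cells, from free RNA or from doublets was not tested here. The all-gene median was 0.10. The class held a different mix of clusters in each library, so proNeu-2, whose share was nearly equal, is set beside it.

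All 9 primary granule genes were higher with Epo (median 0.40, percentile 100), among them the proteases Prtn3 (0.57), Ctsg (0.53) and Elane (0.36). Secondary and tertiary granule genes had 10 of 15 lower (-0.08, percentile 0.03), with Mmp9, a gelatinase, at -1.09 (137 against 293 CPM), Mmp8, a collagenase, at -0.76, but Camp at -0.09 and Ngp at -0.01. Mature neutrophil genes had 14 of 16 lower (-0.30, percentile 0), with the protease inhibitor Stfa2l1 at -1.17, Retnlg, a secreted protein of mature neutrophils, at -1.19 and S100a8 at -0.22. With proNeu-1 included the medians were 0.34, -0.11 and -0.31, and processing alternatives moved the primary granule value over 0.24 to 0.57 and the secondary over -0.21 to -0.079. Within proNeu-2 alone primary granule genes were at 0.06 (percentile 82.3) and mature neutrophil genes at -0.08 (percentile 8.81), yet Retnlg (-1.04), Mmp9 (-1.04) and Mmp8 (-0.82) were about as low as in the whole class. Granulocyte and monocyte transcription factors had 7 of 9 higher (0.16, percentile 89.4), with Klf4, a monocyte factor, at 0.58 and Cebpe, which drives late granules, at 0.15. In proNeu-2 Cebpe was at 0.20, but Klf4 was at -0.51 (-0.79 to -0.24) and Irf8 at -0.87. Receptors were split (9 of 16 higher, 0.08, percentile 46.4), Csf1r at 0.88 and Cxcr4, which retains neutrophils in marrow, at -0.65. Cell cycle genes had 15 of 16 higher by little (0.06, percentile 34.6), with Mcm3 and Mcm6, both of DNA replication, at 0.36 and 0.35.

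Of the island macrophage genes 19 of 21 were higher in the granulocytic cells of the Epo library (1.17, percentile 100). The complement genes C1qa and C1qc were at 2.27 and 2.23, and Vcam1, the adhesion molecule by which macrophages hold erythroblasts, at 0.61 (0.53 to 0.68, 69.9 against 45.9 CPM). By cluster Vcam1 was at 0.26 in proNeu-2, 0.57 in preNeu-2, 0.26 (-0.00 to 0.52) in preNeu-3 and 4.31 in immNeu (85 against 10 UMIs). Recycling genes had all 15 higher (0.45, percentile 100), with Hmox1, which breaks down haem, at 1.14 and the iron exporter Slc40a1 at 0.30. Efferocytosis genes had 11 of 14 higher (0.96, percentile 100), the uptake receptor Lrp1 at 0.87. Red cell membrane genes had all 16 higher (0.72, percentile 100), Rhag at 1.46 and Ermap at 1.28, beside erythroid factors (0.21, percentile 87.8, Klf1 high), iron handling (0.18, percentile 93.0, Tfrc at 0.78), haem synthesis (0.15, percentile 69.5, Cpox at 0.79), autophagy (0.05, percentile 30.1) and haemoglobin (0.05, percentile 40.2). The haemoglobin value joins clusters that ran opposite ways, with medians of 2.62 in proNeu-2, where Hbb-bs was at 2.64 (426 against 81 UMIs), 1.59 in preNeu-2, 1.43 in immNeu and -1.72 in preNeu-3. Further high genes were Pf4, a platelet chemokine also made by macrophages (3.32, 2.89 to 3.81, 315 against 47 UMIs), the antibody-joining Jchain of plasma cells (2.28), the chemokine gene Ccl5 (1.84), Eno3 (1.68) and Ace (1.67). Among genes of other cell types, those of macrophages and red cell membranes stood above random lists in the pooled granulocytic cells of the Epo library. The pooled medians of the other red cell lists did not. Since haemoglobin was higher in proNeu-2, preNeu-2 and immNeu, no contrast between red cell lists is drawn from this.

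Interferon response genes had 13 of 14 higher in the granulocytic cells (0.38, percentile 100), with the chemokine Cxcl10 at 0.78 and Ifit3 at 0.75, but 11 of 13 lower in proNeu-2 (-0.22, percentile 2.38), where Ly6e was at -0.36 (-0.45 to -0.26). All 12 genes of the dissociation and immediate early list were higher (0.62, percentile 100). Among them were Hspa1a, a heat shock chaperone (1.16), Jun (1.11) and Fos (0.61). Fos was also higher in erythroid cells and in each macrophage-named and monocytic cluster compared. With 1 library each, a difference in cell handling cannot be told apart from a response of the cells. MHC class II had 6 of 7 higher (0.27, percentile 98.3), H2-DMa at 0.48, but all 6 measured lower in proNeu-2 (-1.11, percentile 0), Cd74 at -1.22. Targets of the Epo receptor and STAT5 were at 0.14 (percentile 63.2) with Socs3, a feedback inhibitor of cytokine signals, at 0.64 and Osm, a cytokine, at -0.47. Growth factors (0.17, percentile 81.2), adhesion (0.09, percentile 50.4) and hypoxia genes (0.04, percentile 17.6) were unremarkable as groups, with Il18 at 1.28 and Tgfb1 at 0.19. B lineage markers had all 8 lower (-0.80, percentile 0), with Ebf1, Vpreb3 (-1.41) and Fcrla (-1.41), and basophil and eosinophil markers had 7 of 8 lower (-0.51, percentile 0.01), Prss34 at -0.62. That value joins opposite clusters, with Prss34 at -4.09 in proNeu-2 (31 against 637 UMIs), -3.07 in preNeu-2, -2.29 in preNeu-3 and 3.36 in immNeu (871 against 211 UMIs). Megakaryocyte markers (0.59), T and NK markers (0.31), endothelial and stromal markers (-0.67) and sex-linked genes (0.18) complete the lists.

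Clusters named for macrophages and monocytes were compared one by one. The B cell gene Cd79a was lower with Epo in each of the 5 clusters compared (-2.24 to -0.45) and Fos was higher in each (0.20 to 0.34), whereas neutrophil genes differed in direction. Mac_c7, which was led by genes of plasmacytoid dendritic cells, held 496 Epo and 356 saline cells and had more RNA of dividing cells with Epo. Cell cycle genes had 14 of 16 higher there (0.72, percentile 100), with Mki67 at 1.12 (0.78 to 1.48), Ube2c at 1.19, Birc5 at 1.04 and Top2a at 0.87. Lyz2, the lysozyme of phagocytes, was at 1.21 (1.03 to 1.40) and the chemokine gene Ccl3 at 0.84, whereas the B cell genes Cd79a and Ebf1 were at -1.87 and -1.83. In Mono_c15 (1008 and 823 cells) interferon response genes were higher (0.36, percentile 100), immediate early genes were at 0.23, and secondary granule genes at -0.23. Haemoglobin (2.12), red cell membrane (1.57) and megakaryocyte (4.43) RNA was also higher in Mono_c15, and B lineage RNA lower (-1.48), with the plasma cell gene Jchain at -4.59. Mono_c23 (366 and 356 cells) ran the other way for neutrophil genes, with secondary granule genes at 0.30 and mature neutrophil genes at 0.20 (both percentile 100), Retnlg at 3.97 (673 against 40 UMIs) and S100a9 at 0.76, and its cell cycle genes were at 0.69. Jchain showed the largest difference there, -5.15 with 50 against 1688 UMIs. In that cluster the top 5% of cells held 62.0% of S100a8 UMIs with Epo and 17.8% with saline. Mono_c13 had secondary granule genes at -0.23, S100a9 at -0.46, Retnlg at -0.91, cell cycle genes at 0.32 and interferon response genes at 0.23, beside Hbb-bs at 2.44 (333 against 41 UMIs) and the natural killer gene Klrd1 at 2.68 (51 against 5 UMIs). Mono_c19 had primary granule genes at -0.31, S100a9 at -0.38, MHC class II at 0.45 and haemoglobin at -2.13. Genes of Mac_c9 were not compared as ratios because the saline library held 18 such cells.

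The fourth question is whether the antibody tags show the same cells at the protein level. Tag values are the mean per cell of a cluster over the mean of all annotated cells in the same library. Raw tag counts depend on staining and depth, and they differed between the libraries (median 442 per annotated cell with Epo and 292 with saline). CD71 tag stood at 2.92 in ERP1 and 5.25 in ERP2 with Epo, and at 1.37 and 3.15 with saline. This ratio was thus higher with Epo in both erythroid clusters. Tfrc RNA ran the same way, with 633 against 293 CPM in ERP2 and 665 against 603 CPM in ERP1. The tag ratio also depends on the cell mix and staining of each library, so more CD71 protein per cell is not shown by it. CD11b ratios of preNeu-2 and preNeu-3, given below, were higher with Epo too, but the CD71 ratio of proNeu-1 was not. Late neutrophil clusters had low CD71 tag (0.63 and 0.77 in immNeu), and the granulocytic cluster proNeu-1 had high CD71 tag in both libraries (2.99 and 3.13). Ter119, a tag of late red cells, lay below the mean in ERP1 (0.81 and 0.78) and ERP2 (0.80 and 0.77), although haemoglobin genes made up 2.41% of UMIs in ERP1 and 0.440% in ERP2 with Epo, above the 0.241% over all annotated cells.

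CD11b tag was highest in preNeu-3 (3.05 with Epo, 2.07 with saline) and preNeu-2 (2.79 and 2.01), and lowest in ERP1 (0.08 in both). F4/80 tag was highest in Mac_c9 (3.92 and 2.60) and stood slightly above the mean in immNeu (1.31 and 1.16). VCAM1 tag was 6.54 and 3.01 in Mac_c9, and also high in the early granulocytic proNeu-2 (3.10 and 3.15), falling stepwise to preNeu-2 (1.81 and 1.55), preNeu-3 (1.14 and 1.008) and immNeu (0.96 and 0.73). The granulocytic cluster proNeu-1 had VCAM1 tag at 2.39 and 2.59. Vcam1 RNA in proNeu-2 was 172 and 143 CPM. CD163, the receptor that takes up haemoglobin bound to haptoglobin, had a tag ratio of 17.51 and 11.15 in Mac_c9. MHCII tag in Mac_c9 was 5.15 with Epo and 14.12 with saline, and CD169, a macrophage sialic acid receptor, was 1.24 and 1.21. Each saline value of Mac_c9 rests on 18 cells, so no direction is drawn from Epo and saline values of that cluster.

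**Figure D2:**
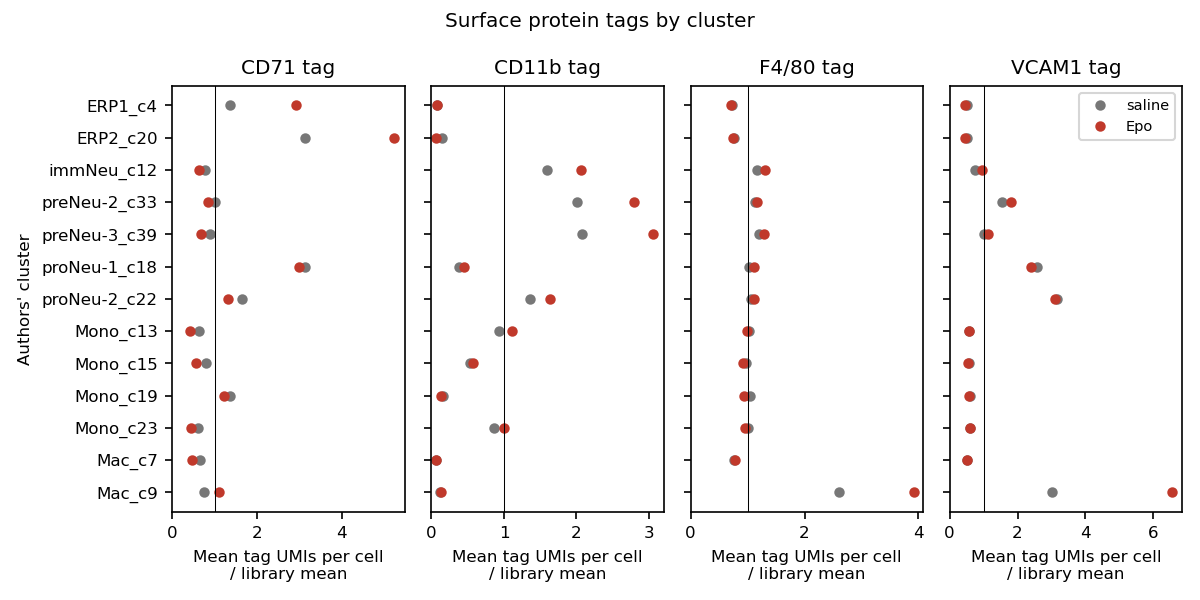
Mean tag UMIs per cell over the library mean (line at 1) for CD71, CD11b, F4/80 and VCAM1, Epo and saline. Shown are the authors' erythroid, granulocytic, monocytic and macrophage-named clusters. CD71 is highest in the erythroid clusters and the granulocytic cluster proNeu-1, and VCAM1 in Mac_c9, proNeu-2 and proNeu-1.

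The fifth question is what unsorted islands contain and what each sort selected. Unsorted islands were mainly erythroid, 45.4% in library 1 and 43.5% in library 2 (mean 44.4%, SD 1.35, n = 2), with a large granulocytic part of 36.2% and 29.3%. Monocytic cells were 3.12% and 5.63%, macrophage-named cells 2.88% and 4.33%. The CD11b+ library was 91.0% granulocytic (89.8 to 92.0, 2537 cells) and 7.60% monocytic, with 0.323% erythroid cells. The CD71+ library was 97.1% erythroid (96.1 to 97.9, 1451 cells), with 1.67% granulocytic cells, 22 of them in proNeu-2, and no monocytic or macrophage-named cell among 1495 (upper limit 0.246%).

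The F4/80+ library was mixed. Clusters outside the erythroid and myeloid classes made up 60.04% (57.4 to 62.7). The cluster named T cell_c13, whose leading genes are those of natural killer cells (Ncr1, Gzma), was at 12.97%, and multilineage progenitors at 10.9%. B cell_c4, whose leading genes include Jchain of plasma cells, was at 8.75%. HSCP-MPP was at 8.01%, and basophils at 3.71% against 0.529% and 0.428% in the unsorted libraries. Mono_c23 was the largest cluster at 23.3%. Macrophage-named clusters made up 9.49% (7.98 to 11.2), but 109 of those 128 cells lay in Mac_c12, led by plasmacytoid dendritic cell genes, and 19 in Mac_c30. Within the granulocytic cells of the CD11b+ library immNeu held 35.2%, preNeu-2 28.5%, preNeu-3 21.99% and proNeu-2 11.8%. In the CD71+ library ERP_c17 held 53.1% of erythroid cells and ERP_c1 25.7%, against 36.5% and 9.49% in unsorted library 1 and 57.6% and 12.0% in unsorted library 2.

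**Figure D3:**
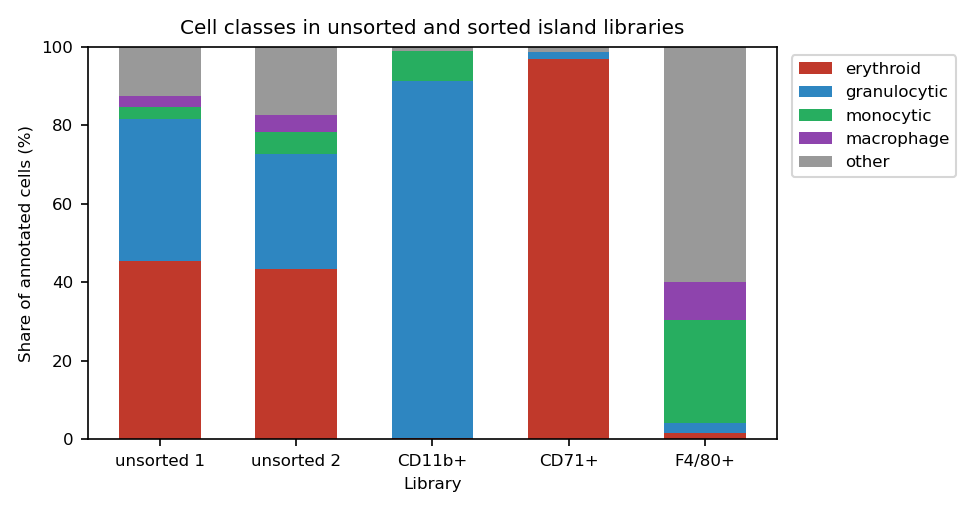
Class shares (%) of annotated cells in unsorted libraries 1 and 2 and in the CD11b+, CD71+ and F4/80+ libraries. Unsorted islands hold erythroid and granulocytic cells, CD11b+ and CD71+ cells are nearly pure, and F4/80+ cells are mixed.

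CD11b+ cells were compared with whole islands to see which genes the myeloid part carries. They held RNA of neutrophil granules at all stages and of glycolysis, and little of red cells, B cells, platelets or macrophages. The all-gene median was -0.75, so medians of the higher lists are given relative to it, followed by the plain log2 value against unsorted library 1. These values thus differ in scale as well as in reference. Medians of the lower lists are plain values.

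All 15 secondary and tertiary granule genes were higher in CD11b+ cells (2.66 relative, 1.90 against library 1, percentile 100), with Ngp at 2.19 (1.90 against library 1), the iron-binding Lcn2 at 2.30 (2.32) and Camp at 1.91 (1.81). Mature neutrophil genes had 15 of 16 higher (1.74, 1.61), S100a9 at 1.82 (1.99), and primary granule genes 8 of 9 (1.65, 0.80), Prss57 at 1.50 (1.17), Ms4a3 at 1.40 (1.009) and Elane at 1.30 (0.80). Hypoxia and glycolysis had 9 of 13 higher (1.32, 0.96), Pkm at 1.85 (1.46). The highest single genes were Ces1d, a carboxylesterase (2.84, 2.13 against library 1), Chit1, a chitinase (2.55, 2.28), Mogat2, of triglyceride synthesis (2.46, 2.01), Lyz2 (2.32, 2.09), Perp (2.29, 2.10), and Orm1 (2.28, 2.12) and Lrg1 (2.28, 1.87), secreted acute-phase proteins. Among transcription factors Cebpe was at 2.08 (1.74) and Irf8, of monocytes and dendritic cells, at -1.78 (-1.46). Vcam1 was at 0.76 (1.12 against library 1), Itgb2, the partner chain of CD11b, at 1.41 (1.69) and the receptor gene Csf2ra at 1.49 (1.68). Cxcr4 was at -2.69 against the mean but 0.06 against library 1, so that difference came from unsorted library 2.

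Lower in CD11b+ cells were haemoglobin genes (plain median -7.16, -7.15 against library 1), red cell membrane genes (-7.62, -7.24, all 16 lower), haem synthesis (-4.47, -4.47), erythroid factors (-4.32, -3.80), iron handling (-2.77, -2.65) and Klf1 (-7.54, -8.02). B lineage markers were at -5.90 (-4.96), and Vpreb3 at least 585-fold lower than the mean, the comparison used for every such bound. The basophil protease gene Prss34 was at least 998-fold lower, Mt2 at least 365-fold and Cd163 at least 22.3-fold. Megakaryocyte markers were at -7.70 (-8.51), T and NK markers at -3.60 (-3.85), and basophil and eosinophil markers at -5.03 (-5.76), or -3.76 with genes at 0 set to their bound. Endothelial and stromal markers were at -6.61 (-5.35), or -4.37 at the bound. Island macrophage genes had 16 of 21 lower (-2.11, -1.25 against library 1), efferocytosis genes were at -2.14 (-1.35) and recycling genes at -0.67 (-0.27). Cell cycle genes had 14 of 16 lower (-0.42, -0.63), Mki67 at -2.54 (-1.34). The recycling and cell cycle medians lay above the all-gene median of -0.75, so against the mean these lists were lower on the plain scale only.

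CD71+ cells were compared in the same way to see which red cell programmes the sort gathered. They were rich in haemoglobin, haem synthesis and membrane RNA and poor in immediate early and receptor RNA. The all-gene median was -1.59, and -0.64 with haemoglobin left out of the totals, so haemoglobin accounts for part of that shift. Relative values are taken from the median of -1.59, so a list can stand high on that scale without being higher on the plain scale. For iron handling, autophagy, cell cycle and primary granule genes no direction is drawn on the plain scale.

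Haem synthesis had all 8 genes higher in CD71+ cells (2.28 relative, 0.43 against library 1, percentile 100), with Alas2 at 1.47 (1.32) and Fech, which inserts iron, at 1.14 (1.19). All 4 haemoglobin genes were higher (2.99, 1.45), Hba-a1 at 1.47 (1.46). Membrane genes had 10 of 16 higher (1.90, 0.51), with Slc4a1, the anion exchanger, at -0.08 against the mean and 0.85 against library 1. Ank1 was at -1.27 (-0.24). Iron handling was at 1.57 relative (0.00 against library 1), autophagy and enucleation at 1.32 (0.06), Bnip3l, which clears mitochondria, at 0.71 (0.90), and cell cycle genes at 1.64 (-0.18), Rrm2 at 1.05 (0.69). Erythroid factors were at 0.98 (-0.25), Klf1 at 0.65 (0.15), Kit at -2.29 (-1.40) and Stat5b at -3.91 (-2.84). Other high genes, again with the value against library 1, were Apol11b (1.87, 1.51), Ube2l6, an ISG15-conjugating enzyme (1.56, 1.39), Isca1, of iron-sulphur cluster assembly (1.52, 1.22), Nanp, of sialic acid synthesis (1.66, 0.76), Nme3 (1.41, 0.52), Plek2 (1.36, 0.78) and Bpgm, which makes the oxygen-releasing metabolite of red cells (1.29, 1.65). Cd36, a fatty acid receptor of earlier erythroblasts, was at 0.84 (1.39).

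Primary granule genes were at 1.48 relative in CD71+ cells (-0.50 against library 1), with Elane at -0.08 (-0.57), beside the proNeu-2 cells that were sorted along. Secondary granule genes were all lower (plain -5.90, -5.93), mature neutrophil genes all lower (-5.24, -4.54), and Mmp8 was at least 710.4-fold and Fn1 at least 260.2-fold lower. Retnlg was at -12.78 (-12.74, interval -15.92 to -11.02), with 2 UMIs left. Immediate early genes were all lower (-2.32 relative, -3.16 against library 1), Fos at -3.55 (-2.87) and Atf3 at least 137-fold. Targets of the Epo receptor and STAT5 had 13 of 15 lower (plain -3.58, -3.10 against library 1, -1.71 at the bound). Lower as well, in plain values, were growth factor receptors (-3.33, -2.27), growth factors (-7.25, -6.32, -4.35 at the bound), adhesion (-3.23, -2.68), island macrophage genes (-4.95, -4.05, -4.48 at the bound), MHC class II (-5.41, -5.45) and hypoxia genes (-1.36, -1.74). The hypoxia median lay above the all-gene median of -1.59, so against the mean that list was lower on the plain scale only.

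F4/80+ cells were compared to learn what a macrophage sort of islands holds. Relative to whole islands, RNA of basophils, T and natural killer cells, antigen-presenting cells and early myeloid cells was enriched, and island macrophage RNA was not. Enrichment does not give the make-up of the library, in which monocytic cells were 26.4% of annotated cells. The all-gene median was 0.34.

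All 8 basophil and eosinophil markers were higher in F4/80+ cells (2.71 relative, 2.58 against library 1, percentile 100), with the proteases Prss34 (3.56, 3.12) and Mcpt8 (3.51, 2.90), beside Fcer1a, the IgE receptor chain (3.89, 3.22). All 6 T and NK markers were higher (2.26, 2.40), Cd3g at 3.28 (2.71) and Cd3e at 3.11 (2.82), beside Izumo1r of T cells (3.68, 3.04) and Ncr1 of NK cells (3.52, 3.21). MHC class II had all 7 higher (1.43, 1.69), Cd74 at 2.11 (1.92) and H2-DMa at 2.54 (2.46). Ass1, of arginine synthesis, was highest (4.15, 3.60 against library 1), followed by the calcium channel gene Cacna1s (3.75, 2.88). Primary granule genes were all 9 higher (plain 0.86, 0.95 against library 1), Ctsc, which activates granule proteases, at 2.74 (3.17) and Ctsg at 1.66 (1.17). Granulocyte and monocyte factors had 8 of 9 higher (0.86, 1.34), Irf8 at 2.48 (2.80), and hypoxia genes 10 of 13 (1.20, 1.14). Jun was at 1.51 (2.12), Fos at 1.50 (2.18) and B lineage markers at 0.68 (1.55).

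Island macrophage genes had 16 of 21 lower in F4/80+ cells (-1.29 relative, plain -0.04 against library 1), with Vcam1 at -1.52 (-1.16). Efferocytosis genes (plain -0.57, -0.06 against library 1) and recycling genes (-0.50, 0.09) were near library 1, with Ftl1 at 0.74 (0.31). Secondary granule genes had 14 of 15 lower (-3.28, -2.69), Camp at -5.77 (-5.88), and mature neutrophil genes 13 of 16 (-3.07, -1.58). Haemoglobin (-6.09, -6.05), membrane (-5.65, -5.52), haem synthesis (-2.96, -3.07) and iron handling (-1.54, -1.56) were lower. Stromal RNA was lower, with Sparc at least 52.4-fold and Cxcl12 at -8.22 (-8.42, interval -14.00 to -6.21) with 1 UMI left.

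Within the class that filled the CD11b+ and the CD71+ sort, the list differences given here were smaller than in the whole sort. For the F4/80+ library the monocytic class was compared, which made up 26.4% of its annotated cells. Its differences were not smaller throughout, and MHC class II genes ran opposite to the whole sort. In CD11b+ granulocytic cells (all-gene median -0.31) secondary granule genes were at 0.25 (0.23 against library 1), primary at -0.03 (-0.38) and cell cycle genes at 0.20 (0.03), with Ces1d at 1.20 (0.48) and Lyz2 at 0.88 (0.50). In CD71+ erythroid cells (all-gene median -1.35) haem synthesis was at 1.29 (plain -0.22 against library 1) and membrane genes at 0.81 (-0.08) relative to all genes, with Ncoa4, which releases iron from ferritin, at 1.26 (1.09 against library 1). In F4/80+ monocytic cells (all-gene median -0.15) primary granule genes were at 0.94 (0.59 against library 1), Elane at 1.47 (1.13), Mpo at 1.35 (1.08) and Ms4a3 at 1.67 (1.10), and cell cycle genes at 0.58 (0.29). Interferon response (-1.45, -0.70 against library 1) and MHC class II genes (-1.37, -0.54) were lower in these F4/80+ monocytic cells. Mono_c23 held 88.2% of them, against 53.8% and 41.9% of monocytic cells in the unsorted libraries, so the cells compared differ in cluster.

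The last question is which island cells carry the molecules by which macrophages hold and feed erythroblasts. Vcam1 RNA was 6674 CPM in Mac_c9 with Epo and 4826 CPM with saline, but it was also present in granulocytic cells, with 69.9 and 45.9 CPM without proNeu-1, and with 109 and 68.3 CPM in the unsorted libraries. Erythroid cells had 1.24 and 0.842 CPM of Vcam1. The ligand chain gene Itga4 was carried by erythroid cells at 215 and 221 CPM, and Icam4, a red cell adhesion molecule, at 75.8 and 74.1 CPM. In the unsorted libraries Icam4 was at 54.5 and 74.8 CPM in erythroid and at 2.47 and 1.60 CPM in granulocytic cells. Epor in erythroid cells of the unsorted libraries was at 88.5 and 83.4 CPM, and in their granulocytic cells at 4.01 and 1.45 CPM.

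Igf1, a growth factor for erythroblasts, was at 804 CPM in Mac_c9 with Epo and 900 CPM with saline, and Kitl, the stem cell factor, at 59.7 (39.7 to 86.3) and 93.5 (40.4 to 184) CPM. Hmox1 was at 3291 and 2524 CPM in Mac_c9, and Slc40a1 at 1760 and 1870 CPM, with 66.4 and 53.9 CPM in granulocytic cells without proNeu-1. Mertk, which takes up dying cells and expelled nuclei, was at 599 and 526 CPM, and Adgre1, which encodes F4/80, at 616 and 596 CPM in Mac_c9. Siglec1, which encodes CD169, was at 78.9 (55.6 to 109) and 164 (89.4 to 274) CPM. Cxcl12 was found in Mac_c30 of the unsorted libraries, at 3850 and 1490 CPM, where stromal genes lead, and not in Mac_c9 (1 UMI with Epo, 0 with saline). Csf3r, the receptor for the neutrophil growth factor, was at 71.1 and 156 CPM in granulocytic cells of the unsorted libraries.

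In mm10 coordinates Tfrc lies at 16:32608920-32632794 (plus strand), Vcam1 at 3:116109949-116129688 (minus strand), Epor at 9:21958897-21963506 (minus strand) and Podxl at 6:31519488-31563981 (minus strand).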

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

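Barcodes to which the authors gave no cluster were looked at as well, 1287 in the Epo library and 1407 in the saline library. Haemoglobin genes made up 1.18% of their UMIs with Epo (1.16 to 1.19) and 0.235% with saline (0.230 to 0.240), against 0.241% and 0.0999% in annotated cells. By marker genes 13.8% (11.9 to 15.8) of these Epo barcodes scored as erythroid against 4.05% (3.08 to 5.22) with saline. Mitochondrial genes took 13.1% of their pooled UMIs with Epo and 8.21% with saline, against 2.16% and 1.92% in annotated cells. The median barcode without a cluster held 8.07% and 4.40% mitochondrial UMIs, and how many of these barcodes were poor cells was not counted. The haemoglobin figures are shares of pooled UMIs, and the median barcode held 0% in both libraries, so they do not count red cells. Barcodes scored as macrophage were 9.01% with Epo and 2.63% with saline. Barcodes scored as erythroid were thus more frequent outside the annotated set with Epo than with saline, and the erythroid shares given above leave them out.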

How the results depend on the processing

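The erythroid share stayed higher with Epo under every alternative. No paired analysis was possible because the labels number replicates only for the unsorted islands, every other group has 1 library, and so the groups share fewer than 2 replicate numbers. The granulocytic share difference of -15.5 points was -13.7 with marker classes scored among annotated cells (scaling the scores over all barcodes gave annotated shares of 24.8% with Epo and 39.6% with saline). The macrophage-named difference of 3.43 points was 1.35 with marker classes, 0.965 in Mac_c9 only and 2.46 in Mac_c7 only. The CD11b+ granulocytic share of 91.0% was 89.7% after the cell filter and 87.8% with marker classes, the CD71+ erythroid share of 97.1% was 94.2% and 90.0%, and the F4/80+ macrophage-named share of 9.49% was 1.33% with marker classes and 1.41% in Mac_c30 only. Among Epo and saline list medians, haem synthesis in erythroid cells moved from 0.11 to 0.17 with TMM. In the whole granulocytic class primary granule genes moved from 0.34 to 0.57 with equal weight per cell, 0.24 with TMM, 0.28 without the doublets of Scrublet's threshold, 0.38 without its highest scores and 0.40 without proNeu-1, and secondary granule genes from -0.11 to -0.15, -0.21, -0.13, -0.13 and -0.079. Island macrophage genes in macrophage-named cells moved from 1.87 to 1.53 with equal weight per cell and 1.18 in Mac_c7 only, but this class is not compared in the text because Mac_c9 made up 83 of its 579 Epo cells and 18 of its 374 saline cells. Leaving haemoglobin out of the totals shifted all genes by -0.34 log2 in the CD11b+, 0.95 in the CD71+ and -0.34 in the F4/80+ comparison. It gave 0.55 for primary and 1.56 for secondary granule genes in CD11b+ cells, 1.66 for haem synthesis, 0.94 for iron handling and 1.28 for membrane genes in CD71+ cells, and 1.42 for MHC class II in F4/80+ cells. With either unsorted library left out the medians ranged over 0.80 to 1.26 for primary and 1.90 to 2.03 for secondary granule genes in CD11b+ cells, -0.38 to 0.0012 for iron handling in CD71+ cells, and 2.58 to 3.22 for basophil and eosinophil markers in F4/80+ cells. The sign depended on which unsorted library was used for adhesion (-0.66 to 0.41), receptors (-0.92 to 1.31) and immediate early genes (-0.78 to 0.84) in CD11b+ cells, for autophagy (-0.83 to 0.063), cell cycle (-0.18 to 0.29) and primary granule genes (-0.50 to 0.40) in CD71+ cells, and for recycling (-0.92 to 0.093), adhesion (-0.58 to 0.35), cell cycle (-0.34 to 0.12), immediate early (-0.44 to 1.28) and megakaryocyte genes (-1.66 to 2.01) in F4/80+ cells. With haemoglobin left out the sign reversed for MHC class II in CD11b+ cells (-0.20), erythroid factors (0.36), autophagy (0.70) and primary granule genes (0.86) in CD71+ cells, and immediate early genes in F4/80+ cells (-0.075). The haemoglobin shifts follow from the construction of the totals, and the cause of the other differences was not tested. In the Epo and saline lists 5 medians stayed the same with 5 UMIs added, with 100 UMIs asked, with no member filter and without haemoglobin. Of the other sorted medians, 31 moved without haemoglobin in the totals, 18 without unsorted library 1, 16 without library 2 and 10 with genes at 0 set to their bound.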

Other observations

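The tests of free granulocyte RNA and of macrophage fragments, and the removal of the highest Scrublet scores, were chosen only after the results had been seen.

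Neutrophil RNA was lower in the erythroid cells of the Epo library, S100a8 at -2.07 log2. Most of it lay in few cells, as saline erythroid cells had a mean of 69.0 and a median of 13 S100a8 UMIs with 81.8% in the top 5% of cells, which free RNA spread evenly over droplets does not give. For the low level in most cells free RNA may play a part, as the saline erythroid median was 2.60 times that of lymphoid cells, between the values set for and against it, and the sources of this level cannot be told apart. Droplets holding an erythroid cell and a granulocyte could give such a few-cell pattern, and without the highest Scrublet scores S100a8 stood at -1.03 (-1.09 to -0.97). Part of the difference remained, so doublets and single cells cannot be told apart.

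The granulocytic share was lower with Epo. The choice of annotated barcodes did not make the difference, which was -12.7 points over all barcodes classed by markers. Among cells of 5000 to 20000 UMIs the difference was -19.7 points. That band kept 900 of 2085 granulocytic cells with Epo and 1784 of 3437 with saline, as their median UMIs were 20712 and 17926. The upper limit thus cut the libraries unevenly, so this value cannot settle the part of depth. Whether the treatment, the animal or the library made the difference stays open with 1 library each.

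Most F4/80+ cells lay outside the macrophage clusters. Fragments of macrophages on other cells may carry F4/80 into the sort. Macrophage marker RNA in lymphoid, progenitor and basophil clusters was 53.8 CPM (47.9 to 60.3) with the sort, 32.4 (26.5 to 39.1) in unsorted library 1 and 45.8 (41.4 to 50.5) in unsorted library 2. It was above library 1 but overlapped library 2, so fragments and true surface expression cannot be told apart by it.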
